A study of Homo sapiens with 2 samples.

How the data were processed

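RNA was sequenced from 2 cultures of the colon cancer cell line HCT116. Per the labels' protocols, the cells grew in medium with fetal bovine serum, RNA was taken with TRIzol, paired-end libraries were made with an Illumina TruSeq V2 kit from 1 µg of total RNA, and barcoded pools were run on an Illumina HiSeq. Reads were processed with TopHat2 2.0.8b and Cufflinks, with the hg19 genome, per the submitters' processing notes, which also list TopHat; the Cufflinks version and the annotation release are not given in the sources used here. The authors deposited 1 table per library with FPKM for each gene, its lower and upper 95% bound and a status, per the file headers. FPKM divides the fragments assigned to a gene by transcript length and by the library's total, so a few abundant RNAs can lower every other value, and genes shorter than a fragment receive unstable values.

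Both tables list the same 56586 genes with versioned Ensembl identifiers. Estimates with status FAIL, 23 genes in PF and 20 in PJ, are listed at 0 although genes that dividing cells use are among them. They were treated as missing, a choice made after the data were seen that departs from the planned count of all rows. Status LOWDATA marks 5988 genes in each table. In PF 2266 genes have an FPKM above their own upper bound and 65 below their lower bound; in PJ the numbers are 2049 and 81. FPKM sums to 3053270 in PF and 3492960 in PJ. The absolute depth is unknown. For genes under 200 bp listed at 0 with an upper bound above 0, that bound times the gene's span was 43.8 in PF and 45.6 in PJ, within 1% for 93.7% and 94.5% of such genes. If the bound stands for the same number of fragments in both libraries, the normalising total of PF was 1.04 times that of PJ.

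FPKM of rows that share a symbol were summed; 375 symbols have several rows. Coordinates are those of the deposited tables (hg19), printed with starts counted from 1. Gene type, transcript length and GC content came from GENCODE release 29 on GRCh38, matched by identifier for 50211 genes, or 88.7%; no coordinate of that release was used. A gene was called expressed at 1 FPKM or more in both libraries. Library differences are log2 ratios, PJ over PF, of FPKM plus a pseudocount of 1, and 2-fold differences were counted among symbols with a mean of 1 FPKM or more. Each side is 1 library, so no p-value was computed.

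Gene lists were written before the data were examined: genes named for or nearest to colorectal cancer risk loci in an earlier and a later list, pathways, markers of colon and other cell types, and culture states, 26 lists in all. A list's level is its median of the mean log2(FPKM + 1), set as a percentile among 10000 random lists of the same size from all symbols, or, to test the choice, from symbols above 0 in at least 1 library. For library differences the random lists were matched on mean expression in 20 bins, for lists with at least 5 members at a mean of 1 FPKM or more. Percentiles describe these 2 libraries. For risk loci, genes whose start lay within 1 Mb of the risk gene's span were searched. Listed symbols absent from the tables (CCAT1, CASC8, CCAT2 and PECAM1) were left out, and older symbols were used where the tables have them.

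The genes named in the text were fixed by a rule written before the data were examined. It takes the 10 highest means; of the risk locus genes the 12 highest means and 8 genes under 1 FPKM in both libraries, in list order; of each other list the 3 highest means and the lowest; the 8 largest log2 ratios in each direction among genes with a mean of 5 FPKM or more; and a few genes fixed by name, among them MSH6, PMS2, TGFBR2, CTNNB1 and CDKN2A. Some genes that the rule selects are not reported here. Other genes were chosen after their values were seen: the nuclear and the protein-coding genes named where the text says so, list members given as examples or exceptions beside a count (CDH1, CLDN3, CLDN4, ELF3, JUN, SESN2, PHGDH, SLC7A11, SOX9, SP5, RNF43, CD44, AURKA, POLD3, TERC), and the genes of the closing paragraphs.

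The counts and list percentiles were tested on simulated libraries with known changes. For the comparison of the libraries, over 15576 genes, the 2-fold count found 48 of 50 genes changed by log2 2, 46 of 50 by log2 -2, 50 of 50 by log2 3 and 50 of 50 by log2 -3, and called 0.969% of 15376 unchanged genes. Of 100 unchanged lists 6 fell outside the central 95%, and 20 of 20 lists shifted by log2 -1 fell below the 2.5 percentile. The simulated noise had a chosen size and was independent between genes. These rates hold for that noise and are not error rates of the real libraries, where genes may move together. Alternatives were other thresholds, pseudocounts, filters and scalings, other random lists, other windows and each library alone. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The normal colon libraries named in the design text were not used here.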

Results

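Gene expression was measured by paired-end RNA sequencing in 2 libraries of HCT116, an epithelial cell line established from a human colon cancer. The submitters describe the libraries as biological replicates of a single group and name them PF and PJ; the labels do not say what these letters stand for. Each library came with an FPKM value (fragments per kilobase of transcript, scaled to the library's total of mapped fragments) and 95% bounds for genes under 51640 symbols. The number of fragments behind each library is unknown, and the deposited bounds were the measure of precision for single values. The design text also names normal colon libraries. These were not analysed here, so the cancer line was not compared with normal colon, and the design leaves 3 questions: which genes the line expressed, whether genes at colorectal cancer risk loci were among them, and how closely the replicates agreed.

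HCT116 cells had transcripts of 14404 gene symbols at 1 FPKM or more in both libraries, 27.9% of the 51609 symbols with a value in each. Among protein-coding symbols the number was 10901, or 57.3% of 19028. The nuclear protein-coding genes with the highest means were ACTG1 (cytoplasmic actin), at 2274 FPKM in PF and 5969 in PJ, the glycolytic enzyme gene GAPDH, at 2297 and 3082, and the ribosomal protein gene RPL8, at 2253 and 2654. NPM1, which encodes a nucleolar protein, stood at 2078 FPKM in PF and 1957 in PJ, and the translation elongation factor gene EEF1A1 at 1762 and 1983. These nuclear genes were chosen after their values were seen. The 10 symbols with the highest means of all, the rule fixed beforehand, were RNAs spanning 57 to 93 bp, 5 of them mitochondrial tRNA genes, and only 2 of the 10 had estimates within their own bounds in both libraries. One of them, AC079949.1, was listed at 346562 FPKM in PF against bounds of 10.8 to 24.2. Genes with a span under 200 bp were 15.7% of the genes and carried 76.9% of the summed FPKM in PF and 79.4% in PJ.

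The series title names colon cancer risk variants, most of which lie outside coding sequence, so the genes around such loci were examined as a list. Of 43 measured genes named for or nearest to risk loci in the earlier of the 2 risk lists, 23 were at 1 FPKM or more in both libraries, or 53.5%, and 13 of these were at 10 FPKM or more in both. The highest was EIF3H (ENSG00000147677.6), a translation initiation factor gene on chromosome 8 (hg19, 117654369 to 117779164), at 373 FPKM in PF (bounds 367 to 388) and 445 in PJ (438 to 462). Its neighbour UTP23 (117778742 to 117861702), for ribosome assembly, was at 17.6 and 32.9 FPKM. MYC (ENSG00000136997.10; chromosome 8, 128747680 to 128753674), the growth-promoting transcription factor gene next to the 8q24 risk region, was at 55.7 FPKM in PF (54.3 to 58.2) and 196 in PJ (193 to 203). BMP4 (ENSG00000125378.10; chromosome 14, 54416454 to 54425479), which encodes a bone morphogenetic protein, was at 53.3 FPKM in PF (50.8 to 55.7) and 311 in PJ (286 to 298).

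CDKN1A (ENSG00000124762.7; chromosome 6, 36644305 to 36655116), the gene of the cell cycle inhibitor p21, showed the opposite order, with 195 FPKM in PF (193 to 202) and 7.71 in PJ (6.84 to 8.59). The cadherin genes CDH3 (chromosome 16, 68670092 to 68756519) and CDH1 (chromosome 16, 68771128 to 68869445), which encode P-cadherin and E-cadherin, were also lower in PJ, at 38.8 and 6.70 FPKM for CDH3 and 21.9 and 1.80 for CDH1. The laminin genes differed in opposite directions: LAMA5 (chromosome 20, 60883011 to 60942368) was at 39.2 FPKM in PF and 24.9 in PJ, and LAMC1 (chromosome 1, 182992597 to 183114727) at 13.7 and 30.3. The transcription factor genes ATF1 (chromosome 12, 51157493 to 51214905) and PITX1 (chromosome 5, 134362615 to 134370503) were at 17.0 and 18.8 FPKM in PF and 39.3 and 32.8 in PJ. LARP4 (chromosome 12, 50786166 to 50873787), an RNA-binding protein gene, was at 10.8 and 25.7 FPKM, and UHRF2 (chromosome 9, 6413151 to 6507054), a ubiquitin ligase gene, at 24.3 and 10.1. For 17 of the 23 expressed genes the estimate lay within its own bounds in both libraries; BMP4, CDH3, LAMC1, UHRF2, POLD3 and TERC were the exceptions.

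**Figure D1:**
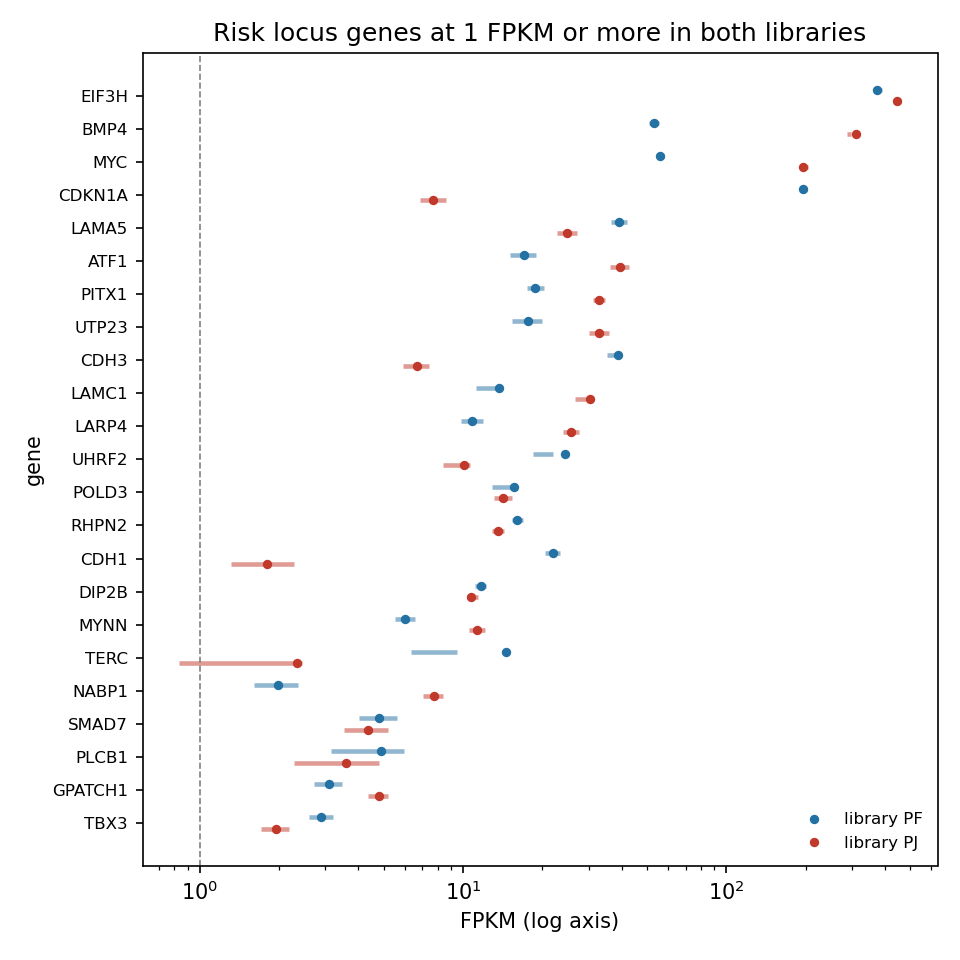
FPKM of the 23 risk locus genes at 1 FPKM or more in both libraries, on a log axis, with library PF in blue and PJ in red. Points are the deposited estimates, bars the deposited 95% bounds, and the dashed line marks 1 FPKM; CDKN1A, CDH3 and CDH1 lie to the left in PJ, while BMP4 and MYC lie to the right.

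The other 20 risk locus genes missed the threshold in at least 1 library, and 15 of them were under 1 FPKM in both. GREM1, a secreted BMP antagonist gene, was at 0.0180 FPKM in PF and 0.0404 in PJ. The transporter gene SLC22A3 stood at 0.000625 and 0.000361 FPKM, the MYC neighbour POU5F1B at 0.0921 and 0.0536, and LRRC34 at 0.523 and 0.382. DUSP10, a phosphatase gene, reached 0.443 and 0.879 FPKM. The 11q23 genes listed as C11orf93 and C11orf53 were at 0.00226 and 0.0222 FPKM in PF and 0.0369 and 0.0243 in PJ, with C11orf92 lower still, and TPD52L3 was listed at 0 in both libraries. Around every one of the 43 genes, including the 20 that missed the threshold, the gene itself or another gene starting within 1 Mb was at 1 FPKM or more in both libraries. This was also true of 497 of 500 randomly drawn protein-coding genes, and risk locus genes had fewer expressed genes within 1 Mb (median 10) than the random ones (median 15). Several of the 43 genes lie at the same locus and share neighbours, as the 11q23 genes do, so these windows overlap and are not separate loci. The median level of the list exceeded that of all 10000 random lists drawn from the full set of symbols, which holds many pseudogenes and short RNAs, but lay at the 53.2 percentile of random lists drawn from protein-coding genes, an alternative chosen after the data were seen. The list of risk loci described later was expressed in full, 12 of 12, led by the tetraspanin gene CD9 at 157 FPKM in PF and 191 in PJ, C11orf10 at 104 and 143, and FEN1, a flap endonuclease gene, at 86.1 and 100.2. Its lowest member, TMEM91, was at 1.68 and 3.46 FPKM.

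The cells carried general epithelial transcripts and almost none of the markers of mature colon cell types. In the intestinal epithelium list, 13 of 20 genes were at 1 FPKM or more in both libraries, with the keratin genes KRT8 at 760 FPKM in PF and 280 in PJ, KRT19 at 306 and 325, and KRT18 at 216 and 147. The homeobox gene CDX1 was at 0.000620 and 0.000410 FPKM. Of 16 absorptive colonocyte genes only CA2 (carbonic anhydrase), at 13.7 and 54.7 FPKM, passed the threshold. KRT20 was at 1.10 and 0.480 FPKM, the sodium-proton exchanger gene SLC9A3 at 0.286 and 0.137, and FABP1 was listed at 0 in both. None of the 12 goblet cell genes passed: FCGBP was at 0.289 and 0.490 FPKM, REG4 at 0.279 and 0.0560, and SPDEF at 0.331 and 0.000104, with TFF3 listed at 0. Among 10 enteroendocrine genes SCG2 alone passed, at 3.21 and 1.15 FPKM, with PYY at 0.00975 and 0.741, CHGB at 0.0486 and 0.0976, and PAX4 listed at 0.

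Markers of other cell types were mostly under the threshold. Expressed members numbered 3 of 12 for fibroblasts, 2 of 9 for endothelium, 2 of 13 for immune cells, 0 of 12 for hepatocytes and 3 of 10 for neurons. VIM, the intermediate filament gene vimentin, was at 4.91 FPKM in PF (bounds 4.33 to 5.49) and 126 in PJ (123 to 130), whereas the collagen gene COL1A1 was at 7.28 and 2.93, SPARC at 3.17 and 1.95, and LUM at 0.000511 FPKM in PF and listed at 0 in PJ. EGFL7 led the endothelial list at 45.5 and 55.2 FPKM, followed by ESAM at 3.07 and 4.67 and ENG at 0.371 and 0.293, and the endothelial cadherin gene CDH5 was at 0.00358 and 0.0117. CD68, a lysosomal protein gene of macrophages, was at 3.46 and 12.6 FPKM, HLA-DRA at 2.52 and 2.34, and MS4A1 at 0.000296 in PF and listed at 0 in PJ. In the hepatocyte list SERPINA1 was at 1.11 and 0.117 FPKM, CYP2E1 at 0.392 and 0.442, TF at 0.338 and 0.240, and FGA was listed at 0. SYT1, which encodes a synaptic vesicle protein, was the highest neuronal gene at 42.4 FPKM in PF and 0.715 in PJ, ahead of GAD1 at 7.19 and 1.95 and GRIN1 at 3.07 and 3.04, with NEFL at 0.0170 and 0.0118. In the cancer-testis list, genes normally confined to the germ line, 2 of 15 passed in both libraries: MAGEA3 at 76.5 and 58.3 FPKM and MAGEA6 at 26.0 and 20.3, near-identical copies whose values are uncertain. MAGEA12 was at 0.498 FPKM in PF and 68.9 in PJ, and CXorf61 was listed at 0.

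Proliferation, ribosomal protein and mitochondrial genome genes were expressed in full, while only some replication histone genes passed the threshold. All 20 proliferation genes passed, among them the replication clamp gene PCNA at 457 FPKM in PF and 264 in PJ, TYMS (thymidylate synthase) at 296 and 266, and the helicase gene MCM7 at 274 and 229; the lowest, E2F1, was at 36.7 and 18.5. All 30 ribosomal protein genes passed, from RPL8, RPLP2 (1673 and 1842 FPKM) and RPS2 (1633 and 1853) down to RPS27A (295 and 297). The 12 mitochondrial genome genes ranged from MT-ND5, at 2394 FPKM in PF and 758 in PJ, to MT-ATP8, at 30550 and 10018, with MT-CO2 at 19316 and 9379 and MT-CO3 at 11432 and 5408. Replication histone genes passed in 6 of 15 cases, with HIST1H2BK at 21.0 and 13.8 FPKM, HIST1H1C at 14.8 and 7.53, HIST2H2AC at 5.83 and 3.61, and HIST1H1D listed at 0. Low values for histone genes need not mean low expression, since how well the libraries captured their transcripts was not examined.

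All 16 genes of DNA mismatch repair and its replication partners passed. MSH3 was the lowest at 1.55 FPKM in PF and 1.14 in PJ, and MSH6 (30.8 and 28.5) and PMS2 (6.83 and 14.1) stood higher; PMS2 has related pseudogenes, and its upper bound was 689 FPKM in PF. POLD2 (166 and 206), RPA1 (70.7 and 100.5) and LIG1 (63.0 and 38.8) led that list. Of 20 genes recurrently mutated or altered in colorectal cancer, 19 passed. CTNNB1, which encodes beta-catenin, was at 129 and 152 FPKM, the Wnt transcription factor gene TCF7L2 at 111 and 36.4, and CDKN2A at 93.5 and 186. The TGF-beta receptor gene TGFBR2 was at 9.92 and 3.01 FPKM and FAM123B at 0.934 and 2.72.

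In the BMP and TGF-beta pathway list, 20 of 24 genes passed, including the BMP-responsive genes ID1 at 104 FPKM in PF and 80.0 in PJ and ID3 at 38.5 and 84.0. Wnt target genes passed in 12 of 20 cases, led by DKK1, a secreted Wnt inhibitor gene, at 49.2 and 546 FPKM and CCND1, the cyclin D1 gene, at 64.8 and 209, and ASCL2 was listed at 0. All 14 p53 target genes, 13 of 15 immediate early genes, 11 of 12 hypoxia genes, 12 of 12 integrated stress response genes, 11 of 12 cholesterol synthesis genes and 6 of 12 interferon response genes passed. The highest of the hypoxia genes were LDHA (487 and 662 FPKM), SLC2A1 (61.4 and 66.5) and VEGFA (20.7 and 21.7), with CA9 at 0.632 and 0.271. Interferon response genes were led by ISG15 (136 and 103) and also held IFI6 (19.9 and 10.0), with OAS1 at 0.110 and 0.00248. For cholesterol synthesis, FDFT1 was at 134 and 162 FPKM, MVD at 56.5 and 86.7, IDI1 at 57.3 and 82.1, and SQLE, the squalene epoxidase gene, at 26.8 and 0.713. List medians for mature colon cells lay within the central 95% of random lists drawn from all symbols (absorptive colonocytes at the 17.2, goblet cells at the 30.4 and enteroendocrine cells at the 24.3 percentile), as did those for fibroblasts (76.7), endothelium (64.8), immune cells (77.5), hepatocytes (60.9), neurons (81.3), cancer-testis genes (81.6), interferon response (95.1) and replication histones (93.2). The remaining lists lay at the 99.7 percentile or above. These positions depend on the random lists: among lists drawn only from symbols above 0 in at least 1 library, absorptive colonocyte genes lay at the 0.1, goblet cell genes at the 1.67 and enteroendocrine genes at the 0.870 percentile, all below the central 95%. Wnt targets moved to the 96.8 percentile, inside it. Among random lists of protein-coding genes, a comparison chosen after the data were seen, the mature colon lists lay lowest again, at 0.03 for absorptive colonocytes and 0.17 for both goblet and enteroendocrine cells. Proliferation, ribosomal protein, mitochondrial genome, mismatch repair, cholesterol synthesis, integrated stress response and later risk locus genes stayed above the central 95% there. Wnt targets (55.1), intestinal epithelium (87.1), the BMP and TGF-beta pathway (89.96), immediate early (90.04), hypoxia (93.6), colorectal driver (94.1) and p53 target genes (96.8) fell inside it, so their high positions among all symbols do not set them apart from protein-coding genes in general.

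The replicates were alike over most genes but differed at least 2-fold in many. Across 37653 symbols above 0 in at least 1 library, log2(FPKM + 1) correlated with Pearson's r = 0.958 and Spearman's rho = 0.895; this is a correlation across genes, which are not independent replicates, and r was 0.890 over symbols with a mean of 1 FPKM or more. Of 15736 symbols with that mean, 1641 were at least 2-fold higher in PJ and 821 at least 2-fold lower on the log2(FPKM + 1) scale, which understates the change of low genes. The whole distribution was shifted, with a median PJ to PF ratio of 1.19 (0.25 on the log2 scale) over the symbols at 1 FPKM or more in both; dividing it out gave 964 higher and 1123 lower. With 1 library on each side, these differences have no replicate check. In 1469 of the symbols higher in PJ and 683 of those lower, the deposited 95% bounds did not overlap; these bounds describe the estimate within a library and leave out variation between cultures, and they were apart for 26 ribosomal protein genes higher in PJ although none of the 30 was 2-fold apart.

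**Figure D2:**
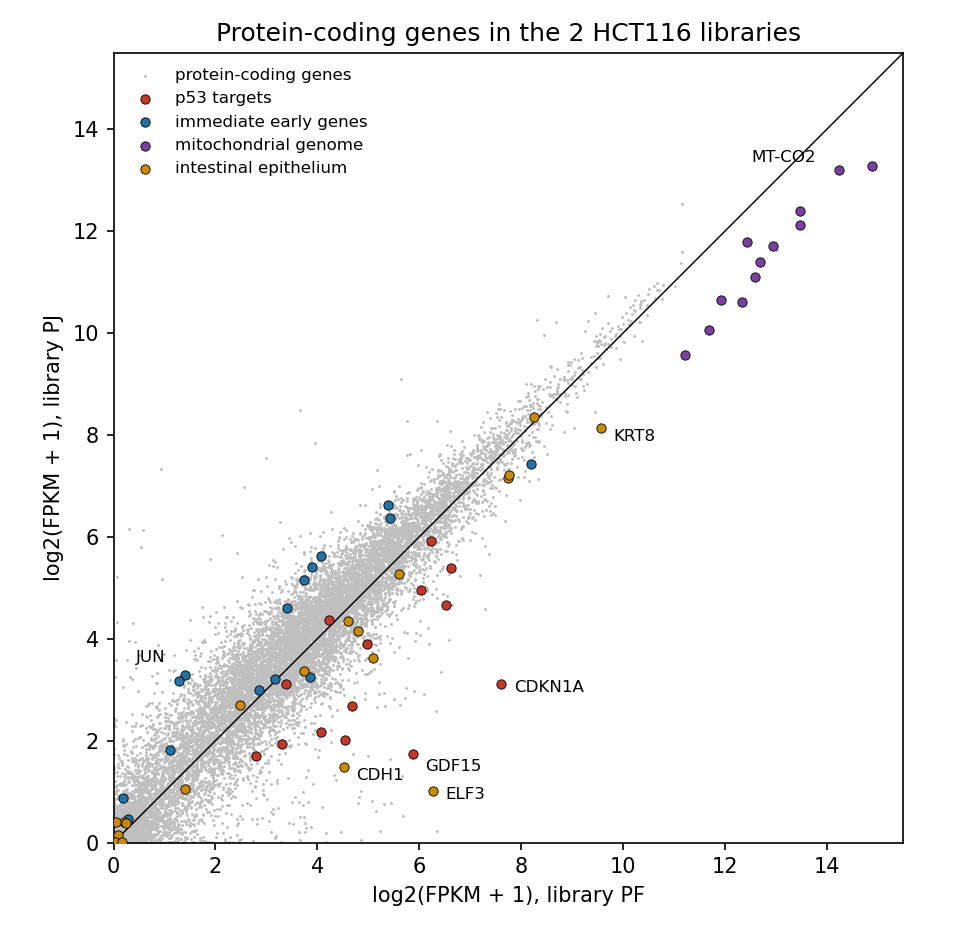
Protein-coding genes above 0 in at least 1 library, as log2(FPKM + 1) in library PF (horizontal) and PJ (vertical), with members of 4 gene lists in colour and the line of equal values. The 12 mitochondrial genome genes and 13 of the 14 p53 target genes lie below the line of equal values, and 11 of the 13 immediate early genes with a mean of 1 FPKM or more lie above it.

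p53 target genes were lower in library PJ. Of the 14 genes, 13 were lower in PJ and 11 at least 2-fold, also after the shift was divided out. Besides CDKN1A, GADD45A (growth arrest) was at 97.6 FPKM in PF and 40.8 in PJ, the proapoptotic gene BAX at 74.4 and 59.6, and the lowest member, ZMAT3, at 5.99 and 2.25. The list's median log2 ratio of PJ over PF was -1.30, under all 10000 random lists matched on expression, whose central 95% ran from -0.10 to 0.58.

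All 12 mitochondrial genome genes were lower in PJ as well, 11 of them at least 2-fold, with a median log2 ratio of -1.33 against a matched range of -0.08 to 0.41. Many of these estimates lay outside their own bounds, as for MT-CO2 in PF (19316 FPKM against bounds of 13108 to 13214). Intestinal epithelium genes had a median log2 ratio of -0.55 (0.01 percentile): 11 of 13 were lower in PJ, 4 of them at least 2-fold, including KRT8, CDH1, the claudin gene CLDN4 (33.3 and 11.3 FPKM) and the epithelial transcription factor gene ELF3 (76.3 and 1.02). KRT19 and CLDN3 were the exceptions. The list's other 7 members, among them CDX1, were under 1 FPKM in both libraries and did not enter this comparison. In the integrated stress response list, with a median of -0.38 (0.15 percentile), ATF4 was at 377 and 276 FPKM, SHMT2 at 138 and 152, PSAT1 at 56.8 and 63.8 and CHAC1 at 1.24 and 1.56. The 3 members at least 2-fold lower as deposited were SESN2, PHGDH and SLC7A11 (4 with the shift divided out).

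Immediate early genes, which growth factors and stress induce within minutes, were higher in PJ, with a median log2 ratio of 1.19, above all matched random lists. Of 13 genes with a mean of 1 FPKM or more, 11 were higher and 7 at least 2-fold (5 after the shift was divided out). FOSL1 was at 41.1 FPKM in PF and 98.0 in PJ, IER2 at 41.9 and 82.0, JUN at 1.66 and 8.82, and EGR2, below the filter, at 0.225 and 0.376, while IER3 was lower in PJ at 292 and 171. Wnt targets had a median of 0.65 (99.5 percentile), with 9 of 14 higher in PJ; DKK1, MYC, CCND1, SOX9 and SP5 were at least 2-fold higher, whereas RNF43 (11.5 and 0.745 FPKM) and CD44 (155 and 23.1) were at least 2-fold lower.

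A further 4 lists also lay below the matched range. Proliferation genes had a median of -0.06 (0.77 percentile) with 10 genes on each side; AURKA, a mitotic kinase gene, was the only one at least 2-fold apart as deposited, at 13.5 FPKM in PF and 66.1 in PJ, and with the shift divided out 13 were lower, 3 of them at least 2-fold. Replication histones (median -0.50, 1.44 percentile) had 6 measured members and none at least 2-fold apart as deposited (1 lower with the shift divided out). Colorectal driver genes (-0.13, 1.02 percentile) and risk locus genes (-0.11, 0.85 percentile) held members on both sides. With random lists matched on transcript length and GC as well, these last lists moved to the 3.12 and 14.8 percentile. That matching kept 22 of the 23 risk locus genes and lost a gene at least 2-fold lower in PJ. The list's own median rose to 0.07, so the matching alone did not move it. The risk locus list moved to 52.3 when only estimates within their own bounds were kept, with 17 members and a median of 0.25. The BMP and TGF-beta pathway list, at the 19.7 percentile otherwise, moved to 0.62 in the same way. Of unrelated lists, 5% would lie outside the central 95% of matched random lists. The lists here share members, such as MYC, CDKN1A and CDH1, and genes within a list may move together. The 5% is therefore no error rate for them. In all, 10 of the 17 lists with 5 or more measured members lay outside that central 95%, 8 below and 2 above. The later risk locus genes (67.8 percentile), BMP and TGF-beta pathway, mismatch repair (22.8), hypoxia (28.7), cholesterol synthesis (87.8), interferon response (20.4) and ribosomal protein genes (35.6) lay within it.

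**Figure D3:**
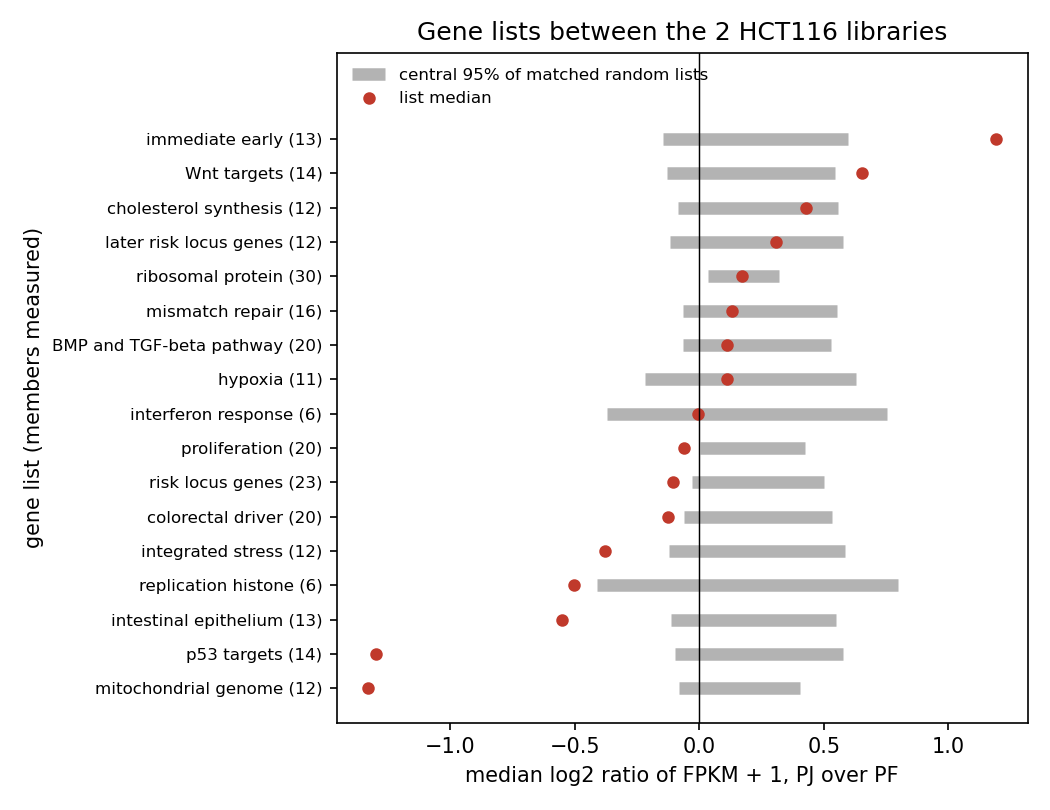
Median log2 ratio of FPKM + 1, PJ over PF, for the 17 gene lists with 5 or more members at a mean of 1 FPKM or more (red points), with the central 95% of 10000 random lists matched on mean expression (grey bars). The mitochondrial genome (-1.33) and p53 target (-1.30) medians lie lowest and the immediate early median (1.19) highest.

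The 8 largest ratios in each direction, fixed beforehand as the single genes to name, belonged to short RNAs: 15 of the 16 span 52 to 107 bp, the other symbol has several rows, and 13 had an estimate outside its own bounds in at least 1 library. The mitochondrial tRNA J01415.3, listed at 25679 FPKM in PF against bounds of 2.86 to 9.53 and at 0 in PJ, is an example. Protein-coding genes were therefore ranked in the same way, a choice made after the values were seen. The lowest in PJ were MAL2, a membrane traffic protein gene, at 80.6 FPKM in PF (bounds 79.1 to 83.4) and 0.177 in PJ (0.0349 to 0.326), then ELF3, the fatty acyl-CoA synthetase gene ACSL5 (50.2 and 0.429), ANXA10 (36.6 and 0.165), the trypsinogen gene PRSS3 (28.0 and 0.0388), SYT1, the cytokine gene IL18 (38.9 and 0.701) and the amino acid transporter gene SLC38A5 (34.6 and 0.533). The highest in PJ were RAB34, a small GTPase gene, at 0.900 FPKM in PF (0.605 to 1.58) and 160 in PJ (155 to 165), the cancer-testis genes MAGEA9B (0.241 and 70.4), MAGEA12 and CSAG1 (0.449 and 54.6), the growth factor gene NRG1 (0.0528 and 35.9), DHRS2 (11.7 and 361), the vitamin D hydroxylase gene CYP24A1 (6.92 and 187) and VIM. MAGEA9B has a near-identical copy, so its value is uncertain. Among nuclear protein-coding genes with 1 row, 28 were at 5 FPKM or more in PF and under 0.5 in PJ, and 17 were the other way round.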

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

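Alternatives that restrict an analysis to protein-coding genes, to estimates within their own bounds, or match random lists on length and GC, and those that take failed estimates as 0, were chosen after the data were seen; the others were planned. The number of expressed symbols (14404) stayed within 1.5 times of itself under every alternative run, from 9820 at a threshold of 5 FPKM to 16068 at 0.5, and the single libraries gave 15375 and 15635. Correlation depended on the filter and pseudocount: r was 0.933 with a pseudocount of 0.01, 0.890 with a mean of 1 FPKM or more, 0.964 without a filter and 0.966 for protein-coding genes. Of 15736 symbols, 2462 were at least 2-fold apart. This became 1565 of 10958 with a mean of 5 FPKM or more and 1050 of 12344 after rescaling both libraries to the same sum. For protein-coding genes it became 1422 of 11394 with the median ratio divided out and 1554 of 10265 within their own bounds. Fewer genes entered each of these, but after rescaling the count fell further than the number of genes. The common sum was below the sum of either library, while the threshold and pseudocount stayed at 1. This rescaling therefore shrinks log2 ratios by itself, and the fall does not show closer replicates. For all symbols with the median ratio divided out, the count was 2087 of 15509. The direction depended on scaling: 66.7% of the differing symbols were higher in PJ as deposited, 46.2% with the median ratio divided out and 49.5% after rescaling to the same sum. With later loci added, 35 risk locus genes were expressed instead of 23, since the list is longer; single libraries gave 24 and 27. The level percentile of the risk locus list was 53.2 against protein-coding random lists, because protein-coding genes are expressed more often than other symbols, and 99.96 to 99.98 in the single libraries. Random lists from symbols above 0 put the 3 lists of mature colon cells below the central 95% and Wnt targets inside it, at 96.8, since many symbols at 0 leave the pool; random protein-coding lists brought 7 of the high lists inside it, from 55.1 for Wnt targets to 96.8 for p53 targets. A window of 500 kb left 41 of the 43 risk locus genes with an expressed gene, the gene itself or a neighbour. Between the libraries, the risk locus list moved from the 0.85 percentile to 14.8 with length and GC matched and to 52.3, on the other side of the median, within bounds. Fewer of its members entered these alternatives, 22 and 17 instead of 23, and its own median changed from -0.11 to 0.07 and 0.25. The colorectal driver list moved from 1.02 to 3.12 with length and GC matched and its 20 members kept, and the cause was not tested. The other 8 lists outside the central 95% stayed outside it under every alternative that gave a value; the mitochondrial and histone lists had under 5 members within their bounds. Of the lists inside it, BMP and TGF-beta pathway genes moved to the 0.62 percentile within bounds. Matching random lists on a length given in the tables was not run, since their length column is empty. Comparisons of the libraries cannot leave either out. No paired analysis was possible because there is 1 group. Unknown depth limits what can be said of values under 1 FPKM.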

Other observations

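Genes at least 2-fold apart in the same direction lay next to each other more often than chance placement gives, a pattern noticed and counted after the data were seen. Among nuclear protein-coding genes with a mean of 1 FPKM or more, 39 pairs of consecutive genes were both lower, against a median of 21 and a maximum of 35 in 1000 shuffles of the genes within chromosomes; for genes higher in PJ there were 171 pairs against a median of 132 and a maximum of 170. The scale matters here: with the median ratio between the libraries divided out, lower pairs numbered 77 against a shuffled median of 46 and a maximum of 70, and higher pairs 59 against a median of 41 and a maximum of 60. Of 27 runs of 3 or more such genes on the deposited scale 21 were higher in PJ and 6 lower, whereas 13 runs with the ratio divided out held 3 higher and 10 lower. The runs named here were present both ways. Overlapping genes were counted as neighbours, and how much they add to the numbers of pairs was not tested. On chromosome 10 (27961803 to 28591995, hg19) the homeobox gene MKX was at 12.6 FPKM in PF and 0.298 in PJ, its neighbour ARMC4 at 5.60 and 0.378, and MPP7, a scaffold protein gene, at 55.6 and 2.33. On chromosome 17 the developmental homeobox genes HOXB2 (4.37 and 0.378 FPKM), HOXB3 (13.1 and 1.67) and HOXB5 (8.76 and 1.92) were lower in PJ, together with SKAP1 (2.84 and 0.00189). In this run HOXB5 lies within the span of HOXB3. HOXB8 (12.6 and 0.150) was lower too but lay outside this run. On chromosome 4 ANXA10 (36.6 and 0.165), DDX60L (24.9 and 2.33) and PALLD (98.8 and 24.3) followed each other, the last of these overlapping DDX60L. Zinc finger genes on chromosome 19 lay in runs of both directions. ZNF440 (5.63 and 0.0227), ZNF700 (6.77 and 0.918) and ZNF136 (2.23 and 0.0420) formed a lower run. So did ZNF600 (3.56 and 0.0232), ZNF28 (7.81 and 0.469) and ZNF468 (3.08 and 0.145), the last of these overlapping ZNF28. ZNF302 (0.799 and 5.24) and ZNF181 (1.74 and 6.05) lay in a higher run. A run higher in PJ on chromosome 11 held MYEOV, CCND1 (64.8 and 209), ORAOV1 (4.58 and 12.1), which overlaps CCND1, and FGF19 (1.61 and 6.18). Medians of the log2 ratio per chromosome ran from 0.12 to 0.41 over 23 chromosomes, leaving out the Y chromosome with 1 measured gene. Medians of 151 windows of 20 Mb ranged more widely, from -0.38 to 0.58.

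Further genes with large differences lay outside these runs. The apolipoprotein genes APOE (3.38 and 64.7 FPKM) and APOC1 (2.71 and 46.6), neighbours on chromosome 19, were higher in PJ. On the X chromosome MAGEA12 and CSAG1 were at 0.498 and 0.449 FPKM in PF and 68.9 and 54.6 in PJ, while MAGEA3 and MAGEA6, close by, were at 76.5 and 26.0 in PF and 58.3 and 20.3 in PJ. The stem cell surface gene PROM1 was at 8.75 and 0.00549 FPKM, and the nuclear receptor corepressor gene NRIP1 at 11.6 and 0.0421. SNAI2, a repressor of epithelial genes, was at 0.0235 and 3.89 FPKM.

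In the paragraphs below, the tests on further lists of p53 targets, G2/M genes, epithelial, mesenchymal and respiratory chain genes were written before those genes were looked at. The tests of length and GC, of another culture or line, of the mitochondrial share and of fibroblasts were chosen after the result was seen, as were the counts with the median ratio divided out. No group in the design gives a biological explanation for any of the patterns, since the labels describe both libraries in the same words.

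p53 target genes were lower in PJ. In a further list of p53 targets, 16 of 23 measured genes were lower in PJ, such as TP53INP1 (13.0 and 0.730 FPKM) and DDB2 (28.9 and 13.8). Only 4 were at least 2-fold lower, and 1, CES2 (5.62 and 12.6), was at least 2-fold higher. The median log2 ratio of -0.38 lay at the 0.03 percentile of matched lists, as lower transcription of p53 targets in the PJ culture would give. Length or GC bias is argued against by the first list, at the 0 percentile of random lists matched on expression, length and GC. The G2/M genes that p53 signalling represses were not higher as a set, at the 4.97 percentile, although CDC20 (92.3 and 221) and CDCA3 (18.6 and 70.7) were. That PJ came from another culture or line than PF could also give such a gap: 45 protein-coding genes were at 5 FPKM or more in 1 library and under 0.5 in the other. In all, 8399 genes were at 5 FPKM or more in PF and 8907 in PJ, and how many such genes cultures of the same line would show is unknown. Without a reference library for each source the culture's state and its identity cannot be told apart.

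Mitochondrial transcripts were lower and other genes higher in PJ. Mitochondrial genes with a span of 200 bp or more accounted for an estimated 9.40% of fragments in PF and 3.96% in PJ, or 7.08% and 3.10% by the middle of their bounds. Through the fixed total this predicts a log2 ratio of the other genes of 0.0841, under the 0.24 observed for nuclear protein-coding genes, so the share may contribute but is too small as the whole source of the shift. The test for fewer mitochondria predicted lower nuclear genes of the respiratory chain in PJ, and they were not lower. Of 26 such genes, 25 were higher in PJ as deposited and 15 with the median ratio divided out. Their median lay at the 94.9 and 94.8 percentile of matched lists. Nuclear transcripts count neither mitochondria nor copies of their genome, so this test cannot exclude fewer of either. Lower transcription or stability of the mitochondrial genome alone was not tested and stays open.

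Epithelial genes were lower and vimentin higher in PJ. A further epithelial list was lower too, with 18 of 23 measured genes lower, such as AP1M2 (58.5 and 6.85 FPKM), S100A14 (85.1 and 9.23) and GRHL2 (5.18 and 0.712). At least 2-fold lower were 6 of them, and 1, ESRP2 (9.07 and 23.1), was at least 2-fold higher. The list's median lay at the 0.01 percentile, as a lower epithelial programme would give. Mesenchymal genes went both ways, 4 of 16 at least 2-fold higher (AXL, SNAI2, ZEB1 and NT5E) and 2 at least 2-fold lower (S100A4 and TAGLN), so that their median, at the 84.2 percentile, leaves a higher mesenchymal programme open; the bound set beforehand would have excluded it, and was too strict for a list that moves apart. Fibroblasts mixed into PJ are argued against by their abundant collagen transcripts: the higher of COL1A2 and COL3A1 was 0.263% of VIM in PJ, and COL1A1 was lower in PJ than in PF. Another culture or line stays open here as for the p53 targets, with the same 45 genes.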
